A study of Cynoglossus semilaevis with 30 samples.

How the data were processed

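Per the labels, RNA was extracted with Trizol from brain, pituitary, liver, gonad and muscle of female Chinese tongue sole aged 1.7 years, the RNA of 2 fish was pooled for each library, and the libraries were sequenced on an Illumina instrument. The deposited table held, for 22292 genes and each of 30 libraries, an FPKM value (fragments per kilobase of transcript, scaled to library size, per the file headers) and an estimated fragment count (per the file headers), of which 2% were not whole (any fraction, with no tolerance). The FPKM values were scaled by the authors to the sum of the estimated counts of the library, as a check of the values showed. The submitters' processing notes name edgeR without a version. Aligner, quantifier and genome build are not given in the sources used here.

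Genes carried 20373 NCBI gene numbers and 1919 locus numbers of an assembly. Symbols were given by the table for 11120 genes and added for 3668 from the RefSeq gene table, to which 19502 gene numbers matched; 7504 genes had no symbol. Groups were formed from size class and tissue, with 3 libraries each. The libraries of large and small females share replicate numbers only and were not treated as pairs.

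Fractional counts were rounded. In each tissue, large females were compared with small by edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test on the 6 libraries, filterByExpr, TMM), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This was the choice set out before the data were examined for a table that holds counts, as were the 39 gene lists, the rule for named genes and the alternatives, except those said to be chosen after seeing the data. The SE of a log2 fold change was its size over the square root of F. Differences between tissues were tested over all 30 libraries by an F test of 4 contrasts, and overlaps of calls by Fisher's exact test for 10 pairs of tissues. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a tissue (39 in brain, 38 in pituitary, 38 in liver, 37 in gonad and 34 in muscle). Of 57 calls of lists, 0 held with an estimated correlation. fry, which asks whether members move on balance 1 way or in either direction, was an alternative. Medians of lists on the FPKM scale are over the members with an FPKM of at least 1 in at least 3 libraries. These can be fewer than the members tested with edgeR.

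Named genes were, per tissue, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group, no overlap of the 3 large and 3 small values and a symbol or product name; for each list described, up to 4 tested members with the smallest p; and genes of the growth and reproductive axes set in advance, whatever their p. Of the last kind, gnrh1, kiss2, fshb and trim63 were matched to no gene by symbol or product name, and ghrh (39 counts in 6 libraries), lhcgr (42), star (6 and 13) and the second myostatin gene LOC103389516 (4) had too few counts to be tested.

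A group at 0 counts was set to 3 counts over the group for a lower bound on a fold, and ratios against 1 to 3 counts have exact Clopper-Pearson 95% intervals; such intervals and floors cover counting error only. Genes typical of a tissue were chosen from these libraries, and their level in other tissues is given in % of the level in the source tissue.

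The tests were checked on simulated data with a known change in 200 genes per tissue. Of genes changed 2-fold, edgeR recovered 28% in brain, 68% in pituitary, 8% in liver, 66% in gonad and 24% in muscle, and of those changed 4-fold 84%, 94%, 76%, 88% and 96%, with 3 to 12 false calls per tissue. The interaction test recovered 82% of genes changed 4-fold in 1 tissue, with 6 false calls. These simulations gave each gene 1 spread for all groups compared and held no RNA of another tissue. Their false calls therefore do not cover size classes of unlike spread, as in pituitary, gonad and muscle, or libraries with foreign RNA.

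The alternatives were DESeq2 1.42.0, limma on log2 FPKM with a pseudocount of 1 or 0.1 and with no filter, median-of-ratios scaling, no filter on low counts, a robust spread, a fit of all 30 libraries, a replicate block, a minimum absolute log2 fold change of 1, and leaving out each library. Chosen after seeing the data were the sum of the 3 libraries of each group in turn, the removal of genes whose median was at least 5 times higher in another tissue, the removal of pancreatic genes from liver, and voom without a correlation. KEGG pathway names were also scanned after seeing the data: of up to 133 tested per tissue, 0, 0, 7, 5 and 16 passed camera in brain, pituitary, liver, gonad and muscle and 0 with an estimated correlation, and they are not described. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.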

Results

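RNA was sequenced from the brain, pituitary, liver, gonad and muscle of female Chinese tongue sole (Cynoglossus semilaevis), a marine flatfish, at an age of 1.7 years. Females of a large and of a small size class were compared. The series' design text names 6 fish in each class, and each library was made from the pooled RNA of 2 fish. Each of the 5 tissues had 3 libraries of large and 3 of small females, which gave 10 groups and 30 libraries. The table held estimated counts and FPKM values for 22292 genes. Library totals ran from 6130671 to 10504899 counts, so that a gene with 0 counts in a library could still stand at up to 0.286 to 0.489 CPM (counts-per-million), counting error only.

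The libraries of 3 groups were nearly alike. Over genes with 100 to 1000 counts, the chi-square per gene between libraries, which is 1 for counting noise alone, was 1.66 to 1.73 in small pituitary, 1.82 to 2.14 in large gonad and 1.65 to 1.82 in small muscle. In the other 7 groups it was 4.36 to 21.1. The libraries differed by more than counting noise and were kept as 3 per group. All p-values rest on the spread between libraries, each of RNA pooled from fish per the labels. Whether the nearly alike libraries came from separate pools is open. Levels below are means ± SD in normalised CPM over 3 libraries, log2 fold changes are large minus small ± SE, and adjusted p-values come from edgeR unless another test is named. The question in each tissue was which genes of the growth and reproductive axes, and which other genes, differed between large and small females of the same age.

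**Figure D1:**
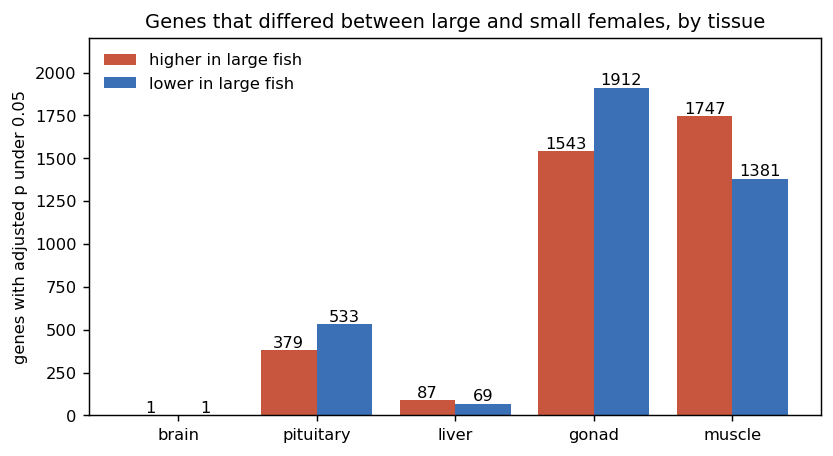
Number of genes (vertical axis) with an adjusted p under 0.05 in each tissue, for genes higher (red bars) and lower (blue bars) in large females. The counts were 1 and 1 in brain, 379 and 533 in pituitary, 87 and 69 in liver, 1543 and 1912 in gonad, and 1747 and 1381 in muscle.

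In the brain, the grancalcin-like gene LOC103389442, named for a calcium-binding protein, rose from 0.0783 ± 0.0678 CPM in small to 20.9 ± 5.91 CPM in large females (n = 3 each). With 2 against 414 counts, the ratio was 256 (exact 95% counting interval 70.4 to 2120; log2 7.76 ± 0.52, adjusted p = 0.00488). LOC103395967, similar to angiopoietin-related protein 4, an inhibitor of lipoprotein lipase in mammals, fell from 40.2 ± 8.76 to 4.196 ± 1.197 CPM (log2 -3.25 ± 0.26, adjusted p = 0.0109). These 2 genes were all that passed edgeR's test among 16878.

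Of the appetite and stress neuropeptides, 26 were tested, 0 passed over all genes, and 0 higher and 7 lower passed when adjusted over the list alone. The list's median log2 fold change was -0.66 (camera adjusted p = 1.77e-13; adjusted p = 0.354 with an estimated correlation). The precursors of melanin-concentrating hormone, which acts on feeding and skin colour in fish, averaged 160 ± 78.8 CPM in small and 7.31 ± 3.91 in large females for pmch (log2 -4.47 ± 0.51, adjusted p = 0.111), and 93.2 ± 32.6 and 6.07 ± 4.70 CPM for pmchl (adjusted p = 0.347). The agouti-related protein gene agrp, an appetite stimulator, averaged 17.8 ± 15.6 and 0.175 ± 0.198 CPM, 440 against 3 counts, a ratio of 119 (exact 95% counting interval 40.3 to 578; adjusted p = 0.24). Galanin (gal) averaged 12.4 ± 2.37 and 4.22 ± 1.46 CPM (adjusted p = 0.435), and npy 10.8 ± 3.14 and 13.1 ± 6.80 CPM (adjusted p = 0.948). The brain aromatase gene LOC103380488, which encodes the enzyme that makes oestrogens, averaged 33.1 ± 11.5 and 60.9 ± 6.03 CPM (adjusted p = 0.609). None of gnrh2, gnrh3, crh, trh, the somatostatin genes sst1.1 and sst1.2, adcyap1a or adcyap1b passed, with adjusted p-values of 0.759 for trh up to 0.9999 for gnrh3.

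Lists of egg and cell cycle genes had a median above 0 in brain, with no gene passing singly. Of 14 vitellogenin and egg envelope genes, 0 passed over all genes and 9 higher and 0 lower passed adjusted over the list alone, with a median of 2.56 (camera adjusted p = 8.58e-10; adjusted p = 0.397 with an estimated correlation). The egg list summed to 61.1, 34.9 and 308 CPM in small and 64.4, 140 and 354 CPM in large replicates 1, 2 and 3, so that small replicate 3 stood above large replicates 1 and 2. Of 57 cell cycle genes 0 passed in either way, and the median was 0.41 (camera adjusted p = 1.27e-11; adjusted p = 0.457 with an estimated correlation). Large brain replicate 3 stood apart here: 231 genes typical of the gonad had a median of 1.48% of their gonad level in it, against 0.265% to 0.576% in the other brain libraries, and the mitochondrial gene mt-co1 took 21.3% of its counts, against 8.22% to 10.7%. Of 20 complement, coagulation and acute phase genes, mostly made in liver, 0 passed over all genes and 0 higher and 3 lower adjusted over the list alone. The median was -1.31 (camera adjusted p = 2.66e-08; adjusted p = 0.397 with an estimated correlation). The 165 genes typical of liver stood at 0.488% of their liver level in small brain replicate 3 and at 0.039% to 0.145% in the other 5.

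The brain count of 2 was 0 without small replicate 1 or small replicate 3, 1 without large replicate 2 or large replicate 3, and 3 without large replicate 1. The adjusted p was 0.0685 and 0.0729 for LOC103389442 without small replicates 1 and 3 and between 0.0583 and 0.107 for LOC103395967 without small replicate 1 or 3 or large replicate 2 or 3. On the FPKM scale, which moved the median of all brain genes by -0.14, limma called 2. An unadjusted p under 0.05 was reached by 1069 genes, and by up to 1423 in other splits of the 6 libraries into 3 and 3. DESeq2 called 94, of which 54 were higher.

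In the pituitary, the growth hormone gene gh1 fell from 28220 ± 1349 CPM in small to 12420 ± 3467 CPM in large females (n = 3 each; log2 -1.18 ± 0.18, adjusted p = 0.00878). The thyrotropin beta subunit gene tshba, whose product stimulates the thyroid, rose from 2180 ± 56.9 to 4445 ± 1287 CPM (log2 1.03 ± 0.18, adjusted p = 0.0168). fkbp5, a chaperone of steroid receptors that glucocorticoids induce in mammals, fell from 427 ± 4.83 to 61.4 ± 29.1 CPM (log2 -2.80 ± 0.30, adjusted p = 0.00224). The gene of the calcium-binding protein calretinin, calb2, rose from 18.4 ± 1.57 to 157 ± 58.5 CPM (log2 3.09 ± 0.26, adjusted p = 0.00103).

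The other hormone genes of the pituitary did not pass. Prolactin (prl) averaged 19570 ± 284 and 22690 ± 5884 CPM (adjusted p = 0.487) and somatolactin (smtla) 10770 ± 454 and 12280 ± 3572 (adjusted p = 0.601). The luteinizing hormone beta subunit (lhb) averaged 21690 ± 749 and 29180 ± 16040 (adjusted p = 0.448), and the common alpha subunit (cga) 22120 ± 469 and 22280 ± 4964 (adjusted p = 0.976). The pro-opiomelanocortin genes LOC103393769, LOC103389827 and LOC103380837 had log2 changes of -0.47, -0.45 and -0.41 (adjusted p = 0.0908, 0.0792 and 0.688), and the transcription factor gene pou1f1 one of 0.30 (adjusted p = 0.0792). Without large replicate 2, prl (adjusted p = 0.000279), LOC103393769 (0.0404), LOC103389827 (0.0189) and pou1f1 (0.00327) passed, and without large replicate 3, smtla (0.00917), LOC103393769 (0.00353) and LOC103389827 (0.00562).

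**Figure D2:**
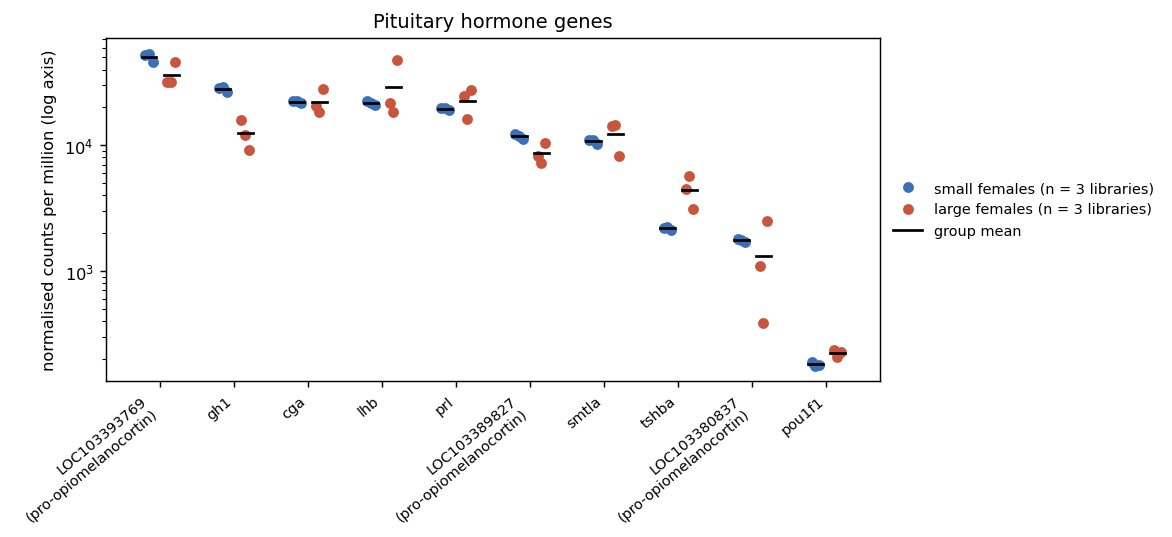
Normalised CPM (log axis) of hormone genes and pou1f1 in each pituitary library of small (blue) and large (red) females, with group means as black bars (n = 3 libraries each). gh1 fell from a mean of 28220 to 12420 and tshba rose from 2180 to 4445, while the 3 small libraries nearly coincided for most genes.

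Among the genes with the largest folds, the grancalcin-like LOC103389442 was at 0 counts in the small and at 345 in the large libraries, at least 105-fold higher (3 counts over the group as the floor; adjusted p = 0.00181). Further rises were those of arhgef25 (3.24), the nr4a1-like LOC103386020 (2.96), dner (2.92), LOC103393046 (promethin-like, 3.63), LOC103391029 (a chemokine, 3.603) and XLOC_009778 (named after an immunoglobulin heavy chain, 2.94). Further falls were those of LOC103383756 (a toxin-binding protein, -3.38), sptssb (-2.85), ccdc37 (-2.78), mgarp (-2.74), mlana (-2.55), hpxb (-2.54) and XLOC_014576 (CD59-like, -2.54), with adjusted p-values for all these of 0.000805 to 0.0341. The calls of arhgef25, LOC103386020, LOC103393046, LOC103391029, XLOC_009778, LOC103383756 and mlana ended without small replicate 1, 2 or 3 (adjusted p = 0.0769 to 0.181), those of LOC103393046 without large replicate 1 (0.0759) and LOC103383756 without large replicate 3 (0.0517), that of sptssb without small replicate 1 (0.0537) and that of XLOC_014576 without small replicates 1 and 2 (0.0774 and 0.0735).

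Genes of secreted blood proteins stood lower in the large pituitaries. Of 18 complement, coagulation and acute phase genes, 0 rose, 5 fell and 13 did not pass, with 1 higher and 12 lower adjusted over the list alone. The median was -1.53 (camera adjusted p = 3.10e-13; adjusted p = 0.132 with an estimated correlation). Antithrombin (serpinc1) fell from 74.0 ± 6.04 to 21.7 ± 3.68 CPM, hemopexin (hpxb) from 37.3 ± 3.08 to 6.40 ± 2.66 and the fibrinogen gamma chain (fgg) from 20.01 ± 1.51 to 4.88 ± 1.46. The 165 liver genes stood at 0.125% to 0.132% of their liver level in the small pituitaries and at 0.028% to 0.074% in the large. Of 34 circadian clock genes, 0 rose, 8 fell and 26 did not pass, with 1 higher and 14 lower adjusted over the list alone. The median was -0.29 (camera adjusted p = 3.29e-06; adjusted p = 0.132 with an estimated correlation). per1 fell from 156 ± 4.80 to 87.1 ± 8.86 CPM, the thyrotroph embryonic factor gene tefb from 193 ± 5.85 to 50.6 ± 20.2 and ciart from 41.3 ± 1.55 to 15.9 ± 4.23, a call that ended without small replicate 1 (adjusted p = 0.0535).

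Immediate early genes, which respond fast to stimuli, moved both ways. Of 28 tested, 7 rose, 2 fell and 19 did not pass, with 11 higher and 4 lower adjusted over the list alone. The median was 0.45 (camera adjusted p = 0.00213; adjusted p = 0.439 with an estimated correlation). The transcription factor gene egr1 rose from 12.2 ± 2.21 to 65.6 ± 15.04 CPM and junbb from 4.45 ± 0.77 to 17.1 ± 2.82, whereas cebpd fell from 197 ± 13.3 to 67.7 ± 15.2. Of 43 collagen and extracellular matrix genes, 0 rose, 9 fell and 34 did not pass, with 3 higher and 11 lower adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.00778; adjusted p = 0.439 with an estimated correlation). This list no longer passed without large replicate 2 (adjusted p = 0.277). col14a1b fell from 150 ± 2.56 to 39.3 ± 13.6 CPM, and the connective tissue growth factor gene ccn2b from 6.45 ± 1.75 to 0.993 ± 0.29, a call that ended without small replicate 1 (adjusted p = 0.0535). Of 23 smooth muscle and endothelium genes, 0 rose, 5 fell and 18 did not pass, with 0 higher and 7 lower adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.000395; adjusted p = 0.132 with an estimated correlation). Of 28 growth hormone and IGF axis genes, 0 rose and 5 fell, with 2 higher and 6 lower adjusted over the list alone, among them socs3 (-1.42), igfbp1a (-1.31) and irs2 (-0.87). The calls of igfbp1a and irs2 ended without small replicate 1, 2 or 3 (adjusted p = 0.0661 to 0.0895). The median of this list was -0.05, and 0.03 on the FPKM scale (camera adjusted p = 0.0484; adjusted p = 0.618 with an estimated correlation). It did not pass without small replicate 1 (0.0868), small replicate 3 (0.0513) or large replicate 2 (0.215).

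The pituitary test passed 379 higher and 533 lower genes of 15668. All 912 showed no overlap between the size classes, as did 29.5% of all genes tested. Chance gives 10% with separate pools, but up to 50% if the 3 small libraries are 1 pool. The count fell to 129, 155 and 148 without small replicates 1, 2 and 3. Each time the calls of gh1 and tshba ended (adjusted p = 0.0577 to 0.0673 for gh1 and 0.102 to 0.111 for tshba). Summed to 1 library, the 3 nearly alike small libraries left 0 genes, with 970 at an unadjusted p under 0.05. Large replicate 2 held 81 genes typical of the brain at 16.3% of their brain level, against 0.468% to 0.625% in the other pituitary libraries, and without it 2386 genes passed.

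In the liver, 6 genes of egg yolk and egg envelope precursors rose from near 0. The vitellogenin-like gene LOC103392840 stood at 0.866 ± 0.676 CPM in small and 23710 ± 29220 CPM in large females (n = 3 each; log2 14.77 ± 1.60, adjusted p = 0.00692), and LOC103392297, vitellogenin-2-like, at 1.23 ± 1.02 and 25930 ± 29810 CPM (log2 14.39 ± 1.57). The vitellogenin-like gene vtg3 rose from 1.58 ± 1.47 to 1335 ± 1357 CPM. The egg envelope genes LOC103380189, LOC103380130 and LOC103380137, of the zona pellucida family, reached 1610 ± 1729, 4952 ± 5585 and 413 ± 480 CPM in large females, from 0.0771 ± 0.134, 2.20 ± 1.61 and 0.439 ± 0.382 CPM. LOC103380189 had 2 counts in the small libraries, a ratio of 21900 (exact 95% counting interval 6050 to 181000). Levels in the 3 large libraries differed widely, from 3467 to 57200 CPM for LOC103392840.

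**Figure D3:**
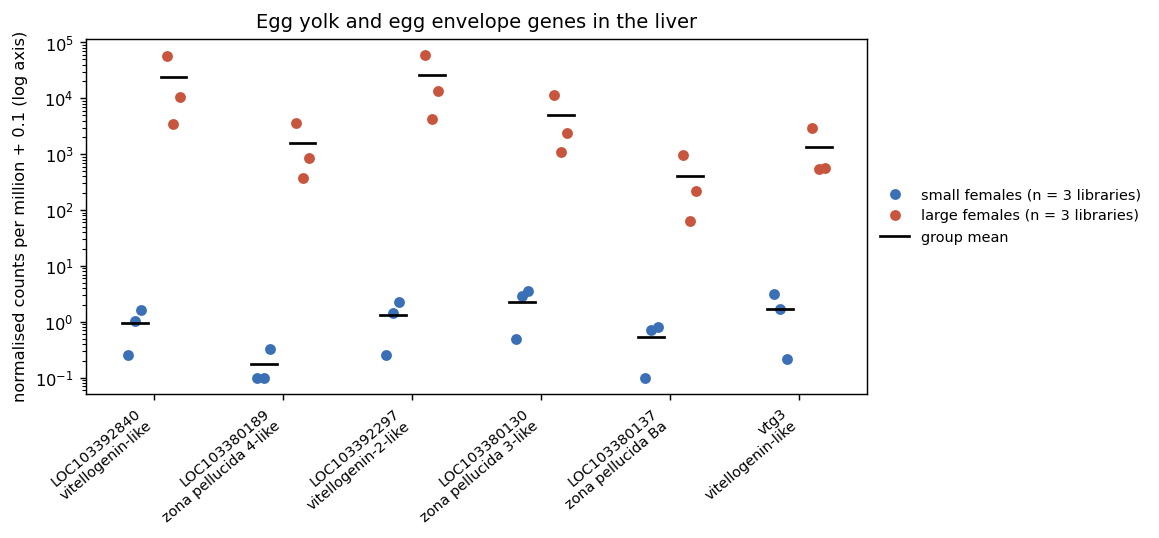
Normalised CPM plus 0.1 (log axis) of 6 egg yolk and egg envelope genes in each liver library of small (blue) and large (red) females, with group means as black bars (n = 3 libraries each). For LOC103392840 the small libraries lay between 0.157 and 1.503 and the large ones between 3467 and 57200 CPM.

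Of 14 vitellogenin and egg envelope genes in the liver, 5 rose, 0 fell and 9 did not pass, with 6 higher and 0 lower adjusted over the list alone. LOC103380137 is not a member of the list. The mean was 4.39 and the median 0.23 (camera adjusted p = 1.66e-05; adjusted p = 0.644 with an estimated correlation, and 0.0654 without small replicate 2). With FPKM the median was -0.13, and 4.13 with FPKM also scaled by median of ratios. These FPKM medians cover only the members kept by the FPKM filter, so members and scale are not told apart. Also higher were nots, a cathepsin D-like gene (0.116 ± 0.20 to 234 ± 248 CPM, 3 against 4011 counts, a ratio of 2120 with an exact 95% counting interval of 725 to 10300), and LOC103386340, a solute carrier at 0 counts in the small libraries and at least 428-fold higher in the large. The estrogen receptor gene esr2 (ncbi-103382676), chosen after its values were seen, rose from 4.77 ± 3.23 to 38.8 ± 2.45 CPM (log2 3.04 ± 0.46, adjusted p = 0.0219), a call that ended without small replicate 2 and each large replicate (0.0658 to 0.116), and esr1 averaged 1.33 ± 0.95 and 4.82 ± 2.04 CPM (adjusted p = 0.117).

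Single genes of metabolism were among the largest falls. The serine-pyruvate aminotransferase gene agxtb fell from 399 ± 171 to 3.12 ± 2.92 CPM (log2 -6.92 ± 0.73, adjusted p = 0.00686). The gene of a key enzyme of gluconeogenesis, pck1, fell from 53.6 ± 54.7 to 0.649 ± 0.366 (log2 -6.22 ± 1.19, adjusted p = 0.0454). The gene of the thyroid hormone inactivating enzyme, dio3b, fell from 77.5 ± 66.6 to 0.974 ± 0.843 (log2 -6.18 ± 0.89, adjusted p = 0.0164). creb3l3, a transcription factor active in fasted liver, fell from 12.5 ± 8.202 to 0.0323 ± 0.056 CPM, 466 against 1 count (ratio 294, exact 95% counting interval 52.5 to 11600). Further falls were those of pltp (-5.04), nat8l2 (-4.44) and eps8l1 (-4.31), the last pair not called without large replicate 1, 2 or 3 or small replicate 2 (adjusted p = 0.0658 to 0.21). The main liver gene of the growth axis, igf1, averaged 72.4 ± 34.6 and 107 ± 43.6 CPM (adjusted p = 0.491) and the growth hormone receptor gene ghr 30.8 ± 3.99 and 56.5 ± 6.34 (adjusted p = 0.0958). None of igf2, igfbp1a, igfbp2 and igfals passed (adjusted p = 0.486, 0.0946, 0.29 and 0.615), but without small replicate 3, igfbp1a (0.0124), igfbp2 (0.0238) and esr1 (0.0168) did.

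Of 23 immediate early genes in the liver, 0 rose, 4 fell and 19 did not pass, with 1 higher and 13 lower adjusted over the list alone. The median was -1.13 (camera adjusted p = 1.02e-09; adjusted p = 0.672 with an estimated correlation). egr1 fell from 104 ± 30.1 to 7.35 ± 2.14 CPM, fosl1 from 20.7 ± 9.81 to 1.47 ± 1.12 and cebpd from 101 ± 33.7 to 17.9 ± 7.77. The gene fosab, a c-Fos-like gene matched to no member of the list, fell from 87.3 ± 47.6 to 2.65 ± 2.18 CPM. Of 36 endoplasmic reticulum stress and chaperone genes, 0 passed over all genes and 0 higher and 11 lower adjusted over the list alone. The median was -0.70 (camera adjusted p = 1.19e-05; adjusted p = 0.672 with an estimated correlation). Of 72 ribosomal protein genes, 0 passed in either way, and 70 stood higher in large females. The median of 0.63 was -0.18 on the FPKM scale (camera adjusted p = 8.77e-09; adjusted p = 0.733 with an estimated correlation). Of 33 fatty acid and triglyceride synthesis genes, 2 rose (scdb, 2.74 ± 0.68 to 11.7 ± 4.54 CPM, and mid1ip1), 1 fell (lpin1a) and 30 did not pass, with 4 higher and 1 lower adjusted over the list alone. The median of 0.35 was -0.19 on the FPKM scale (camera adjusted p = 0.0136; adjusted p = 0.672 with an estimated correlation, and 0.112 without small replicate 2).

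Genes of the pancreas took a larger mean share of the counts in the large liver libraries. Of 9 exocrine and endocrine pancreas genes, 0 passed over all genes and 8 higher and 1 lower adjusted over the list alone. The median was 1.92 (camera adjusted p = 0.000339; adjusted p = 0.672 with an estimated correlation). All 46 pancreatic genes together took 4.96%, 9.25% and 19.4% of the counts in small and 33.5%, 15.7% and 38.2% in large libraries. Without them, 90 genes rose and 73 fell.

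The liver test passed 87 higher and 69 lower genes of 11878, all 156 without overlap (25.9% of all genes tested; chance gives 10%). On the FPKM scale, which moved the median of all liver genes by -0.62, limma called 96 higher and 1053 lower. With FPKM also scaled by median of ratios it called 95 and 60, and DESeq2 called 460 and 305. The count was 17, 37 and 34 without large replicates 1, 2 and 3, 40 without small replicate 2 and 1209 without small replicate 3. The calls of pck1, creb3l3 and dio3b ended without each large replicate (adjusted p = 0.0677 to 0.22) and that of pck1 also without small replicates 1 and 2 (0.0531 and 0.094), those of agxtb and pltp without large replicate 1 (0.0669 and 0.0534), that of fosab without large replicates 1 and 3 (0.0743 and 0.0802), and those of the 6 egg genes in no case. The calls of fosl1, cebpd, lpin1a, scdb and mid1ip1 ended without small replicate 2, large replicate 1 or large replicate 2 (adjusted p = 0.0637 to 0.214), all of these but scdb also without large replicate 3, and mid1ip1 also without small replicate 1 (0.0922).

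In the gonad, the growth factor gene bmp3 was at 0 counts in the small libraries and at 44.2 ± 7.19 CPM in the large, at least 390-fold higher (n = 3 each; adjusted p = 2.31e-05). The serotonin receptor gene LOC103383821 (at least 171-fold), the grancalcin-like LOC103389442 (at least 123-fold), LOC103390181, similar to bmp10 (at least 86.5-fold), and fgl1 (at least 52.5-fold) were likewise at 0 counts in the small libraries. The aromatase-like gene LOC103378914 rose from 2.32 ± 1.36 to 10.95 ± 0.78 CPM (log2 2.20 ± 0.35, adjusted p = 0.00343). fshr rose from 1.02 ± 0.12 to 3.87 ± 1.17 CPM (log2 1.91 ± 0.38, adjusted p = 0.00737). The table's symbol is that of the follicle-stimulating hormone receptor, but its product name is that of the luteinizing hormone receptor.

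The phosphate transporter gene slc34a1 fell from 44.3 ± 3.29 to 5.59 ± 0.59 CPM (log2 -2.98 ± 0.15, adjusted p = 1.78e-05) and LOC103398100, a ribonuclease P subunit-like gene, from 51.3 ± 12.7 to 1.92 ± 0.34 (log2 -4.74 ± 0.25, adjusted p = 1.78e-05). XLOC_010562, for which the symbol and the product name in the table name different genes, was at 0 counts in the large libraries and at least 99.2-fold lower. Further rises were those of ttc36 (1 against 160 counts, ratio 128, exact 95% counting interval 22.6 to 5080), LOC103383836 (SPARC-like, 4.60) and LOC103389013 (apolipoprotein C-I-like, 4.43), and further falls those of serpind1 (-5.02), ccr10 (-3.76), camsap1 (-3.62), LOC103399862 (-3.21) and LOC103376708 (-2.99). The oocyte growth factor genes gdf9 (451 ± 57.9 and 404 ± 18.9 CPM, adjusted p = 0.319) and bmp15 (573 ± 47.4 and 496 ± 8.71, adjusted p = 0.143) did not pass, nor did foxl2, amh, cyp17a1, igf1 and igf3 (adjusted p = 0.167, 0.199, 0.829, 0.86 and 0.074).

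Ribosomal protein genes fell together in the large gonads. Of 72 tested, 0 rose, 69 fell and 3 did not pass, with 0 higher and 71 lower adjusted over the list alone. The median was -0.81 (camera adjusted p = 2.60e-39; adjusted p = 0.695 with an estimated correlation). rpl3 fell from 2595 ± 42.4 to 1253 ± 17.8 CPM and rps15a from 1006 ± 75.2 to 552 ± 17.5. Of 83 oxidative phosphorylation genes, 2 rose, 50 fell and 31 did not pass, with 3 higher and 57 lower adjusted over the list alone. The median was -0.54 (camera adjusted p = 1.14e-12; adjusted p = 0.695 with an estimated correlation). ndufb6 fell from 244 ± 31.5 to 115 ± 10.1 CPM and cox4i1 from 645 ± 18.7 to 387 ± 35.9. The mitochondrially encoded mt-co1, picked on seeing the data, took 0.052 ± 0.032% of the counts in small and 0.492 ± 0.040% in large gonads, the opposite way. Of 43 proteasome genes, 1 rose and 14 fell, over all genes and adjusted over the list alone. The median of -0.26 was 0.05 on the FPKM scale (camera adjusted p = 0.00445; adjusted p = 0.695 with an estimated correlation).

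Genes of the egg envelope and of the oocyte stood lower. Of 24 vitellogenin and egg envelope genes, 1 rose, 13 fell and 10 did not pass, with 1 higher and 15 lower adjusted over the list alone. The median was -0.45 (camera adjusted p = 0.000166; adjusted p = 0.695 with an estimated correlation). The egg envelope gene LOC103392929 fell from 8774 ± 1469 to 5241 ± 159 CPM and LOC103394278 from 1973 ± 297 to 1044 ± 77.1. Of 28 oocyte and germ cell genes, 1 rose, 9 fell and 18 did not pass, with the same counts adjusted over the list alone. The median of -0.22 was 0.03 on the FPKM scale (camera adjusted p = 0.00445; adjusted p = 0.695 with an estimated correlation). zar1l fell from 1341 ± 30.5 to 638 ± 37.2 CPM, and tdrd1 rose from 23.99 ± 1.54 to 40.9 ± 3.20. Of 59 cell cycle genes, 1 rose, 18 fell and 40 did not pass, with 1 higher and 19 lower adjusted over the list alone. The median of -0.19 was 0.12 on the FPKM scale (camera adjusted p = 0.0149; adjusted p = 0.695 with an estimated correlation, and 0.0899 without small replicate 3). Of 37 collagen and extracellular matrix genes, 7 rose, 2 fell and 28 did not pass, with 9 higher and 2 lower adjusted over the list alone. The median was 0.78 (camera adjusted p = 0.00445; adjusted p = 0.695 with an estimated correlation). col1a1a rose from 43.1 ± 31.6 to 126 ± 9.03 CPM, a call that ended without large replicate 1, 2 or 3 (adjusted p = 0.0640 to 0.0784), and lum from 0.545 ± 0.353 to 3.01 ± 0.825.

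The gonad test passed 1543 higher and 1912 lower genes of 14123. Of these, 99.3% showed no overlap, as did 45.9% of all genes tested (chance gives 10% with separate pools, but up to 50% if the 3 large libraries are 1 pool). On the FPKM scale, which moved the median of all gonad genes by 0.30, limma called 3735 higher and 775 lower. With FPKM also scaled by median of ratios it called 1281 and 1851. The count fell to 1355, 1221 and 1134 without large replicates 1, 2 and 3, and the call of camsap1 ended without large replicate 1 (adjusted p = 0.0505) or 2 (0.0517). Summed to 1 library, the 3 nearly alike large libraries left 7 higher and 5 lower genes, bmp3 (adjusted p = 0.00669) and slc34a1 (0.0213) among them.

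In muscle, genes of eggs, oocytes and dividing cells rose together in large females, and genes typical of the gonad stood higher. Of 25 vitellogenin and egg envelope genes, 24 rose and 1 did not pass, with the same counts adjusted over the list alone. The median was 1.88 (also with the member at 0 counts at its bound; camera adjusted p = 3.72e-15; adjusted p = 0.273 with an estimated correlation). zp3f.1 rose from 44.8 ± 4.94 to 165 ± 56.8 CPM (n = 3 each). Of 25 oocyte and germ cell genes, 19 rose, 0 fell and 6 did not pass, with 20 higher and 0 lower adjusted over the list alone. The median was 1.62 (camera adjusted p = 1.28e-11; adjusted p = 0.395 with an estimated correlation), and h1m rose from 76.9 ± 3.88 to 230 ± 66.9 CPM. Of 57 cell cycle genes, 46 rose, 0 fell and 11 did not pass, with 50 higher and 0 lower adjusted over the list alone. The median was 1.51 (camera adjusted p = 6.10e-25; adjusted p = 0.395 with an estimated correlation). ccnb1 rose from 31.5 ± 1.43 to 89.4 ± 21.2 CPM and ube2c from 8.55 ± 1.14 to 32.5 ± 9.26. The 231 gonad genes stood at 1.71% to 1.74% of their gonad level in the small muscle libraries and at 3.94%, 10.1% and 3.55% in the large. Of the 1747 genes that rose in muscle, 1577 (90.3%) had a median at least 5 times higher in another tissue, against 59.9% of the genes tested, and 1422 of them were highest in the gonad.

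**Figure D4:**
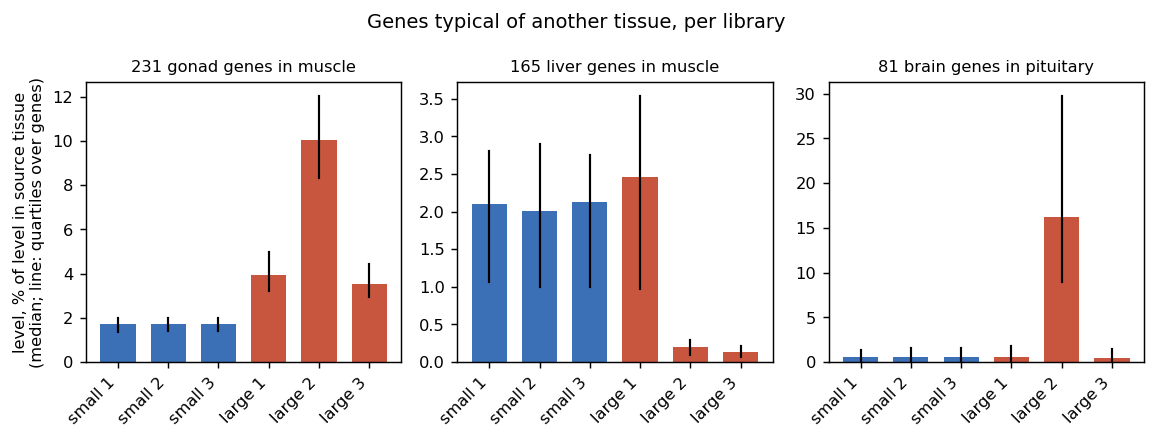
Median level, in % of the level in the source tissue, of 231 gonad and 165 liver genes in each muscle library and of 81 brain genes in each pituitary library (bars; lines span the quartiles over genes; small females blue, large red). Gonad genes stood at 3.55% to 10.1% in large and 1.71% to 1.74% in small muscle, liver genes at 2.01% to 2.13% in small and 2.47%, 0.203% and 0.14% in large muscle, and brain genes at 16.3% in large pituitary replicate 2.

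In the muscle of large females some genes of growth hormone and IGF signalling fell. Of 21 tested, 1 rose, 6 fell and 14 did not pass, with 1 higher and 7 lower adjusted over the list alone. The median was -0.61 (camera adjusted p = 3.83e-05; adjusted p = 0.273 with an estimated correlation). The growth hormone receptor-like gene LOC103389092 fell from 14.5 ± 1.05 to 2.95 ± 0.62 CPM (log2 -2.32 ± 0.23, adjusted p = 0.00102), socs3, a feedback inhibitor of cytokine and growth hormone signalling, from 22.3 ± 1.58 to 4.94 ± 1.93, and igfbp1a from 8.99 ± 0.42 to 1.45 ± 0.97. igf1 itself fell from 4.44 ± 0.68 to 1.93 ± 0.47 CPM (log2 -1.23 ± 0.33, adjusted p = 0.0237), a call that ended without large replicate 2 (adjusted p = 0.0542) and without small replicates 1, 2 and 3 (0.0592, 0.103 and 0.0851). Liver RNA was not removed from this list, and igf1 stood higher in liver, as given above. Genes typical of liver stood at 0.203% and 0.14% of their liver level in large muscle replicates 2 and 3, below small muscle. How far this made up the falls was not tested. igf2, igf1r, ghr, the myostatin gene LOC103392395, myog, myod1 and the ubiquitin ligase gene fbxo32 did not pass (adjusted p = 0.664, 0.365, 0.592, 0.708, 0.984, 0.274 and 0.101), but myod1 (0.0144) and fbxo32 (0.0302) did without large replicate 3.

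Of 29 glycolysis genes in muscle, 2 rose, 1 fell and 26 did not pass, with a median of 0.07 (camera adjusted p = 0.996), and the share of the list in the counts was 15.9 ± 0.192% in small and 20.9 ± 3.77% in large muscle. Of 28 fatty acid oxidation genes, 0 rose and 8 fell, over all genes and adjusted over the list alone. The median was -0.38 (camera adjusted p = 0.000807; adjusted p = 0.395 with an estimated correlation). cpt1b, which admits fatty acids to mitochondria, fell from 72.1 ± 3.62 to 24.5 ± 9.76 CPM, and pdk4, which limits glucose oxidation, from 14.6 ± 1.71 to 5.57 ± 1.07. Of 33 muscle atrophy and autophagy genes, 1 rose and 9 fell, over all genes and adjusted over the list alone. The median was -0.45 (camera adjusted p = 0.000807; adjusted p = 0.159 with an estimated correlation), with ulk2, a kinase that starts autophagy, falling from 14.6 ± 1.46 to 6.45 ± 0.54 CPM. Of 22 gluconeogenesis and glycogen genes, 2 rose and 8 fell, over all genes and adjusted over the list alone. The median was -0.35 (camera adjusted p = 0.00198; adjusted p = 0.173 with an estimated correlation), with gyg1b, a primer of glycogen synthesis, falling from 240 ± 4.03 to 86.0 ± 23.0 CPM. The member g6pc, at 218 CPM in small liver, was not called. It stood at 5.72 to 7.45 CPM in small muscle and at 6.04, 0.0833 and 0 CPM in large replicates 1, 2 and 3. Genes typical of liver, given below, differed in the same way, and liver RNA was not removed from these lists. Of 27 immediate early genes, 1 rose, 11 fell and 15 did not pass, with 1 higher and 12 lower adjusted over the list alone. The median was -0.77 (camera adjusted p = 3.29e-05; adjusted p = 0.159 with an estimated correlation). dusp1 fell from 124 ± 6.93 to 44.9 ± 15.4 CPM, and junbb rose from 20.3 ± 1.64 to 44.4 ± 7.39. Of 17 erythrocyte genes, 1 rose and 7 fell, with 2 higher and 9 lower adjusted over the list alone. The median was -0.79 (camera adjusted p = 0.000414; adjusted p = 0.159 with an estimated correlation). The alpha globin gene hbae5 fell from 1864 ± 24.7 to 1045 ± 84.7 CPM.

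Largest among the rises was that of f13a1, a coagulation factor gene, from 0.0847 ± 0.147 to 15.9 ± 10.8 CPM, 2 against 481 counts (ratio 231, exact 95% counting interval 63.7 to 1920). It was followed by LOC103380130, LOC103379025 (mucin-like), noxo1b, LOC103392840, LOC103393422 (a keratin), LOC103392297 and zg16 with log2 changes from 4.49 down to 3.59. The calls of the egg genes LOC103380130, LOC103392840 and LOC103392297 ended without small replicate 1, 2 or 3 (adjusted p = 0.0704 to 0.115). Of the falls, agxtb stood at 8.49 ± 0.94 and 0.11 ± 0.125 CPM, 215 against 3 counts (ratio 74.5, exact 95% counting interval 25.1 to 364). The gene cyp24a1, which inactivates vitamin D, fell by 4.52 on the log2 scale, and the small heat shock protein gene LOC103390125 fell from 65.0 ± 1.201 to 5.32 ± 2.81 CPM. Angiotensinogen (agt, -3.66), smtnl2 (-3.603), amylase (-3.46), LOC103390470 (-3.35) and LOC103394098 (-3.26) also fell. agxtb, cyp24a1, agt, amylase and LOC103394098 are at least 26.4 times higher in liver. The 165 liver genes stood at 2.01% to 2.13% of their liver level in small muscle and at 2.47%, 0.203% and 0.14% in large muscle replicates 1, 2 and 3.

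The muscle test passed 1747 higher and 1381 lower genes of 13301, of which 99.4% showed no overlap, as did 43.5% of all genes tested (chance gives 10% with separate pools, but up to 50% if the 3 small libraries are 1 pool). Genes at least 5 times higher in another tissue made up 1577 of the rises and 392 of the falls. A new fit without such genes, with scaling and spread estimated anew, passed 449 higher and 557 lower. The balance of rises and falls among the remaining genes thus depended on the fit. The count was 1330, 1253 and 1371 without small replicates 1, 2 and 3, and with the 3 nearly alike small libraries summed to 1 it was 0, with 1921 at an unadjusted p under 0.05. DESeq2 on the 6 libraries called 3090, and limma on FPKM 1506 with a pseudocount of 1, 1483 with one of 0.1 and 666 without a filter. With FPKM also scaled by median of ratios, limma with a pseudocount of 1 called 1585 higher and 1282 lower.

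**Figure D5:**
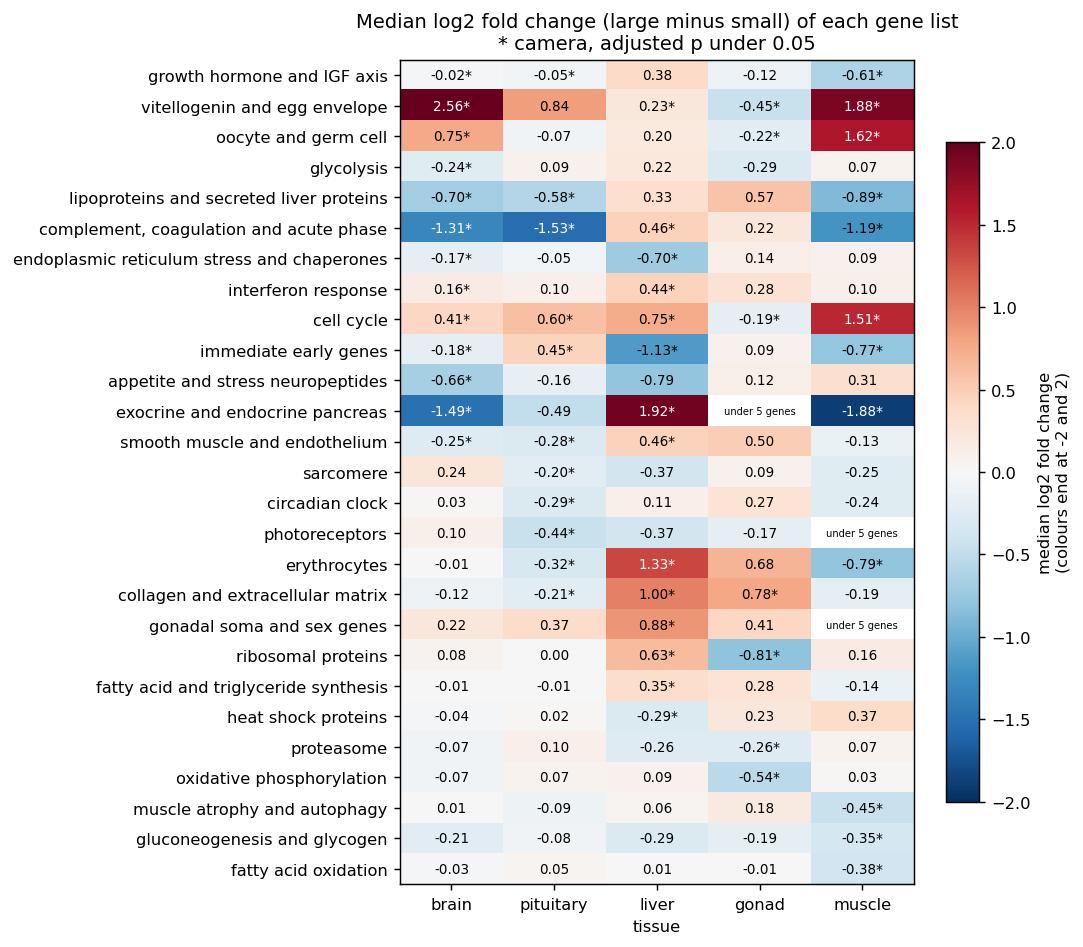
Median log2 fold change, large minus small, of the lists (vertical) that passed in at least 1 tissue, in each tissue (horizontal), with an asterisk for a camera adjusted p under 0.05; colours end at -2 and 2. On another scaling the median had the other sign for 13 of the 57 passing lists, 8 of them in liver and 3 in gonad, and with an estimated correlation 0 passed. FPKM medians cover only members kept by the FPKM filter, so the sign can change with the members as well as the scaling.

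The last comparison asked whether the effect of size differed between tissues. It did for 5049 of 19511 genes (edgeR, F test over 4 contrasts), among them 53 of the 101 genes named by the rule. The rule chose part of these named genes for a large change within a tissue. The test gave each gene 1 spread over all 10 groups, although the spread differed between groups. In a fit of all 30 libraries with 1 spread per gene, liver calls numbered 2367 against 156, and pituitary calls 291 against 912. Unlike spread can thus raise or lower the count of 5049. RNA of other tissues was not removed first and can add to this count. Gonad genes stood at 3.55% to 10.1% of their gonad level in large muscle, and brain genes at 16.3% in large pituitary replicate 2. The c-Fos-like gene fosab rose in the pituitary and fell in liver and muscle (log2 1.56 ± 0.33 in pituitary, -4.94 ± 0.64 in liver and -2.45 ± 0.28 in muscle; adjusted p of the differences 1.57e-06 and 0.00188). Its call in the pituitary ended without any 1 library but large replicate 2 (adjusted p = 0.0564 to 0.153). The vitellogenin-like gene LOC103392840 fell in the pituitary (-2.30 ± 0.30) and rose in liver (adjusted p of the difference 1.11e-05). For gh1, LOC103389442 and prl the difference between tissues did not pass (adjusted p = 0.592, 0.887 and 0.564). The count was 2285 without small replicate 1 and 1536 without small replicate 2 of all tissues.

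Calls in different tissues overlapped in part. Gonad and muscle shared 207 genes called in the same and 533 in opposite directions, of which 411 fell in the gonad and rose in muscle, where independent lists would share 234. Of genes with an absolute log2 fold change of at least 1, 27 did so, where independent lists would share 26.1. Of the 1747 genes that rose in muscle, 1422 were at least 5 times higher in the gonad. How far gonad RNA in muscle made up the opposite calls was not tested. Pituitary and muscle shared 96 genes that fell in both, where independent lists would share 39.4 (Fisher's exact test of all calls, adjusted p = 8.66e-06), and liver and muscle shared 37 called in the same and 10 in opposite directions (adjusted p = 8.11e-07). Libraries of 2 fish each would use all 6 fish of a class in every tissue, but whether a replicate number stands for the same fish in each tissue is not given in the sources used here. Libraries of the same number correlated by 0.045 to 0.144 among small brain, liver and gonad. In large fish they correlated by 0.078 to 0.135 between brain and pituitary and 0.05 to 0.172 between pituitary and liver. Large liver and muscle gave 0.045 to 0.099, large brain and liver 0.001 to 0.053, and large pituitary and muscle -0.001 to 0.16. Large brain and muscle went the other way, with -0.075 to -0.014 for the same number and up to 0.127 for different numbers. Pairs with a nearly alike group stood, for the same number, at -0.04 to 0.056. In voom, 1 correlation for the same size and number was estimated at 0.00737. As not all pairs went 1 way, these values leave the question open. The F test took the 30 libraries as independent, which would not hold if a number marks the same fish.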

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

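All tests of explanations in this part were chosen only after the result was seen; the tests of differences between tissues were planned. Effects that differed between tissues singled out the results of this paragraph and the next. The 3 patterns weighed after them were picked on seeing the data. The effect of size differed for 5049 genes, and over 25 label sets, the real one and 24 with size labels redrawn within each tissue, 1 gave as many, with 887 genes the highest of the others. As 3 groups of libraries nearly coincide and redrawn labels break them up, this leaves chance open. Within a tissue the 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 2 genes in brain, 912 in pituitary, 156 in liver, 3455 in gonad and 3128 in muscle, and the highest other 1, 1, 0, 0 and 0, so that 1 split reached the real count in each.

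Named genes were called in opposite directions in a pair of tissues, with a test of the difference. As the genes were picked for such calls in the same libraries, a small p of the difference adds no separate support. The nr4a1-like LOC103386020 had a log2 change of 2.96 ± 0.47 in pituitary and -1.18 ± 0.26 in muscle (difference 4.07, adjusted p = 0.000637). XLOC_009778, named after an immunoglobulin heavy chain, had 2.94 ± 0.56 and -1.99 ± 0.40 in the same tissues (difference 4.84, adjusted p = 0.00973). The vitellogenin-like LOC103392840 had -2.30 ± 0.30 in pituitary, against 14.77 ± 1.60 in liver (difference -16.95, adjusted p = 1.11e-05) and 3.75 ± 1.07 in muscle (-6.14, adjusted p = 0.0231). LOC103392297 had -2.22 ± 0.25 in pituitary, against 14.39 ± 1.57 in liver (-16.50, adjusted p = 6.82e-06) and 3.59 ± 0.95 in muscle (-5.90, adjusted p = 0.02). For fosab the pituitary stood apart from liver by 6.52 (adjusted p = 1.57e-06) and from muscle by 3.95 (adjusted p = 0.00188). esr1 had -1.32 ± 0.11 in pituitary and 1.25 ± 0.37 in gonad (-2.53, adjusted p = 0.0166), and slc34a1 -2.98 ± 0.15 in gonad and 2.12 ± 0.58 in muscle (-5.23, adjusted p = 1.51e-05). Of these, some calls ended without 1 library: those of LOC103386020 and XLOC_009778 in pituitary without any 1 small replicate (adjusted p = 0.0769 to 0.125), as did those of LOC103392840 and LOC103392297 in muscle (0.0834 to 0.115), and that of fosab in liver without large replicate 1 (0.0743) or 3 (0.0802). The call of fosab in pituitary ended in all cases but without large replicate 2 (0.0564 to 0.153), that of esr1 in gonad in all but without small replicate 3 (0.0685 to 0.156), that of slc34a1 in muscle without any 1 small replicate or large replicate 2 (0.0756 to 0.109), and that of LOC103386020 in muscle without small replicate 2 (0.0562) or 3 (0.0533).

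The 3 libraries of small pituitary, of large gonad and of small muscle nearly coincided. A tissue with little spread between fish is argued against by the same tissues in the other size class, where the lowest chi-square per gene was 4.36. In large muscle, unlike shares of gonad and liver genes add to the spread, so it is not that of the tissue alone. A low spread between fish in only 1 size class is not covered by this comparison. Whether each of these groups came from 1 pool of RNA was not tested. Taken as n = 1, with their libraries summed, they left 0 genes called in pituitary, 12 in gonad and 0 in muscle. In data simulated with the spread of the other class, this summed design recovered few changes. In pituitary, gonad and muscle it found 0%, 2% and 0% of genes changed 2-fold, and 64%, 68% and 30% of those changed 4-fold. A lost call therefore does not tell no change from low power. The log2 fold changes hardly moved, with -1.19 for gh1 (-1.18 unsummed), 1.02 for tshba (1.03) and -2.80 for fkbp5 (-2.80) in pituitary.

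Genes typical of the gonad stood higher in the large muscle libraries, with egg, oocyte and cell cycle genes. Gonad RNA in the muscle libraries is a candidate explanation: the upper quartile of the marker shares was at most 1.54 times the lower in a large library, as 1 share of foreign RNA would give. As the cause of the falls in large muscle it is argued against, since its share of at most 10.07% could lower a gene by a log2 ratio of -0.153 at most. Falls called in 2 large and 2 small libraries had, in the library pairs left out, a highest median log2 ratio of -0.758. The egg genes LOC103380130, LOC103392840 and LOC103392297 were among the largest rises in muscle. Their median gonad level was at most 0.000155 of their median level in large liver, but it was not set against their level in muscle. Genes typical of liver stood at 2.47%, 0.203% and 0.14% of their liver level in large muscle replicates 1, 2 and 3. What brought these egg genes to muscle was not tested. Whether gonad RNA in muscle came from the dissection, the library or the sequencing was not tested.

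Vitellogenin and egg envelope genes stood higher in the large liver libraries. Gonad RNA is argued against: the highest ratio of the median gonad level to the median large liver level over the 6 genes was 0.000155. The unequal share of pancreatic genes and the scaling are argued against too, with a lowest log2 fold change of 6.45 over the genes and alternatives. A biological difference may underlie the pattern, as a hypothesis; the stage of maturity of the fish is not given in the sources used here, and it was not tested against size.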

How the results depend on the processing

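Summing libraries, leaving out genes 5 times higher elsewhere or pancreatic genes, and voom without a correlation were alternatives chosen after seeing the data; the others were planned. Over settings other than leaving out 1 library, named genes kept direction and side of the threshold in 1281 cases, lost the call in 113 and gained it in 39, and lists did so in 1531, 147 and 136. With the 3 large libraries summed, calls numbered 0 in brain (675 at an unadjusted p under 0.05, edgeR), 3961 in pituitary, 0 in liver (711), 12 in gonad and 6063 in muscle. With the 3 small libraries summed they numbered 0 (230), 0 (970), 283, 6681 and 0 (1921). Summing leaves 1 library in a group, assumed to vary like the other group. With small pituitary, large gonad or small muscle summed in simulated data, 0%, 2% and 0% of genes changed 2-fold were recovered. DESeq2 gave 94 in brain and 765 in liver. The fit of all 30 libraries gave 53 in brain, 291 in pituitary, 2367 in liver and 1943 in gonad. With the replicate block there were 10 in brain, 597 in pituitary and 253 in liver. limma on FPKM without a filter gave 607 in pituitary, 24 in liver, 666 in muscle and 8254 for the interaction; with a pseudocount of 0.1 it gave 841 in liver and 1483 in muscle, and with 1, 1149 in liver, 1506 in muscle and 8151 for the interaction. Without a count filter liver had 627. Without genes 5 times higher elsewhere, brain had 1 and muscle 1006, with fewer genes tested and the scaling and spread estimated anew. With an absolute log2 fold change of at least 1, 388 remained in pituitary, 1186 in gonad and 2019 in muscle. Calls shared by a pair of tissues then numbered 111 in the same and 111 in opposite directions, against 477 and 691. These are sums over the 10 pairs, in which a gene can count more than once. Leaving out 1 library gave 0 to 3 calls in brain, 129 to 2386 in pituitary, 17 to 1209 in liver, 1134 to 3965 in gonad and 1253 to 3897 in muscle. For the interaction, leaving out 1 replicate number of a size class in all 5 tissues gave 1536 to 4120. Lists passing camera numbered 13 in brain, 11 in pituitary, 14 in liver, 7 in gonad and 12 in muscle. With an estimated correlation they numbered 0 in each tissue; with fry 0 in brain, 1 in liver and 11 in gonad; with fry in either direction 8, 33, 22, 34 and 29; without genes 5 times higher elsewhere 7 in brain, 9 in liver and 7 in muscle; on FPKM with either pseudocount 3 in gonad; and leaving out 1 library 11 to 18, 9 to 14, 12 to 18, 7 to 8 and 12 to 17. Cell cycle in pituitary reversed without genes 5 times higher elsewhere (camera adjusted p = 0.805), and myelin and glia in pituitary with the 3 large libraries summed (2.54e-10). limma on FPKM with a pseudocount of 1 was also run after median-of-ratios scaling. It then called 95 higher and 60 lower in liver, 1281 and 1851 in gonad and 1585 and 1282 in muscle. The median shift of a gene from edgeR was then 0.02 in liver and -0.015 in gonad. In these tissues the departures of limma with that pseudocount thus went with the scaling. For the other settings the cause was not tested. Depth limits genes near 0.286 to 0.489 CPM.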

Other observations

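All values in this part were chosen after the data were seen, and so was the test. The grancalcin-like gene LOC103389442 was alike in several tissues: the small libraries held 0 counts in pituitary, liver, gonad and muscle and 2 in brain, and the large libraries averaged 19.7 CPM in brain, 15.2 in pituitary, 1.97 in liver, 15.5 in gonad and 1.91 in muscle, before normalisation. XLOC_009764, with no product name, went the other way, with 5.04 CPM in small brain, 6.34 in small pituitary, 5.76 in small liver and 3.23 in small muscle, against 0 counts in large brain, liver and muscle and 4 in large pituitary; the gonad held 1 count in small and 1 in large. Of 61 genes called in 3 or more tissues, 9 rose and 12 fell in each tissue that called them. In the gonad, mt-co1, the mitochondrial gene of cytochrome oxidase, rose from 568 ± 347 CPM in small to 4437 ± 391 CPM in large females (n = 3 each; edgeR adjusted p = 0.00143).

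fkbp5 did not pass in brain (log2 -1.85, edgeR adjusted p = 0.295), liver (-2.64, adjusted p = 0.0972) or gonad (-0.41, adjusted p = 0.225). This gene, which glucocorticoids induce in mammals, fell in pituitary and muscle, and a hypothesis is that lower glucocorticoid signalling in large fish explains this. A list of 19 other such genes was tried, some of them, such as per1, dusp1 and pdk4, already seen to fall, and 11 in a fixed list whose result had been seen. The median was below 0 with an unadjusted camera p under 0.05 in 4 tissues of 5. The medians, with camera p adjusted over 5 tissues, were -0.10 in brain (adjusted p = 0.0112), -0.07 in pituitary (adjusted p = 0.00256), -0.43 in liver (adjusted p = 0.000715) and -1.30 in muscle (adjusted p = 2.54e-07), against -0.01 in gonad (adjusted p = 0.723). Over all genes 0, 4, 2 and 10 members fell in brain, pituitary, liver and muscle, and 2 rose and 2 fell in gonad. Liver RNA, which differed between muscle libraries, was not removed. The member tat, which fell in muscle from 15.2 to 6.21 CPM, averaged 460 CPM in small liver. How far liver RNA made up the falls in muscle was not tested. With the 8 members in no fixed list only 2 tissues had a median below 0 and an unadjusted camera p under 0.05, liver and muscle (adjusted p = 0.0953 and 0.00908), and with an estimated correlation 0 passed. tsc22d3, another target in mammals, rose in gonad (log2 1.26 ± 0.23, adjusted p = 0.00554) and did not pass elsewhere (log2 0.29 in brain, -0.08 in pituitary, 1.146 in liver and 0.31 in muscle). With an estimated correlation on all 19 no tissue passed (adjusted p = 0.105, 0.0791, 0.107, 0.726 and 0.0791 in brain, pituitary, liver, gonad and muscle). The values leave the hypothesis open: they may reflect lower signalling, handling of the fish or feeding, which were not told apart, and cortisol is not given in the sources used here.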
